A study of Mus musculus with 16 samples.

How the data were processed

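DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in mouse cells. RRBS cuts genomic DNA with MspI, which enriches for fragments rich in CpG, and bisulfite then converts unmethylated cytosines so that they are read as thymine. Per the labels' protocols, DNA was digested with MspI, gap-filled and A-tailed with Klenow enzyme, ligated to methylated adapters, converted with bisulfite, amplified for 15 PCR cycles and sequenced on an Illumina NovaSeq instrument with reads of 150 bp. Per the submitters' processing notes, the tools were fastp 0.20.1, Bismark 0.23.0, Bowtie2 and methylKit, and the genome build was GRCm39. Trimming settings, the removal of filled-in cytosines at fragment ends, duplicate handling and mapping options are not given in the sources used here. End repair writes cytosines of its own at MspI ends, which could lower or raise the level at those sites in all libraries alike. The libraries hold no molecular identifiers per the labels' protocols, so reads were not counted as independent molecules.

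The authors' deposited tables are CpG tables in the layout of methylKit, 1 per library, and each line gives the chromosome, position, strand, coverage and the percent of reads called C and called T. Coverage is a count of reads at the site, per the file headers, and the freqC and freqT columns are percent values in the deposited tables. The smallest coverage was 10 reads in each library, so sites with fewer reads are not listed. Coverage times percent methylated gave a whole number of reads, within rounding of the printed percent, at each listed site, and 0 sites were not whole in any library. These methylated and unmethylated read counts were the input of all tests. The strands of a CpG are listed separately and were kept as separate sites.

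Group and replicate came from the labels. The 16 libraries fell into 8 groups of 2, which were D0, D2, D4, D6, D8, D10, D12 and iPSC. The labels give no statement that the replicates came from separate cultures or embryos, so p-values measure only the spread between these samples, which may be technical. The libraries listed between 1480222 and 2516218 sites, the sum of coverage lay between 39011213 and 107834007 reads, and the median coverage lay between 18 and 27 reads. The same sites were compared in all groups by keeping those covered by at least 10 reads in all 16 libraries, which left 873038 of 3179510 sites, or 27.5%. Replicates were compared before averaging. Across the common sites, the Pearson r between replicates was 0.964 in D0, 0.955 in D2, 0.939 in D4 and 0.907 in D6. It was 0.799 in D8, 0.786 in D10, 0.600 in D12 and 0.942 in iPSCs. The mean chi-square per site between replicates, which is near 1 for sampling noise alone, lay between 2.09 and 2.99, so no pair was treated as 1 library. That reference value assumes independent reads, so a value above 1 does not show that the replicates were separate cultures.

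Before the data were examined, promoters and CpG islands were chosen as the units of the tests, with lists of pluripotency, fibroblast, germline and imprinted genes. The gene table at hand belongs to GRCm38.p6, not to the build of the deposited sites, and no genome sequence of either build was used here. Promoters, CpG islands, MspI sites, gene lists, imprinting windows and named genes were therefore not analysed here. Tiles of 1 kb that held at least 3 common sites took their place, in the same test and with the same thresholds, which gave 94337 tiles on chromosomes 1 to 19, X and Y. Tiles are given as chromosome, start and end on GRCm39, counted from 1, and which gene lies there was not looked up. The median tile held 6 common sites and 260 reads per library, and the 5th and 95th percentiles of reads were 72 and 1231. As a measure of CpG density, the distinct CpGs listed in any library were counted per tile, in classes of 1 to 4, 5 to 9, 10 to 19 and 20 or more. Only CpGs listed with at least 10 reads are counted, so the number also depends on how much of a tile RRBS covered. The terms CpG-rich and CpG-poor below refer to this count. These classes and the classes of D0 level were chosen after the files had been opened.

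Methylation levels of a tile are methylated reads over all reads at its common sites, and levels of a group are the mean and SD over its 2 libraries. The main test was edgeR 4.0.16 quasi-likelihood (glmQLFit and glmQLFTest, R 4.3.3) on methylated and unmethylated counts, with an effect for each library, a methylation coefficient for each group and a common dispersion, all 16 libraries in 1 fit and 8 residual degrees of freedom. A tile was called when its Benjamini-Hochberg adjusted p was under 0.05 and the group means differed by at least 10 percentage points. The 3 main contrasts were iPSC against D0, D12 against D0 and iPSC against D12. D2 to D10 were each compared with D0, and a joint test asked for any difference among D0 to D12. Global levels were means over the common sites, compared by exact two-sided permutation tests, which cannot go below 0.333 with 2 libraries against 2, and by a permutation test of the correlation with day (100000 permutations). For each main contrast and direction, the named tiles are the 5 with the largest difference among calls in which every library of 1 group lay above every library of the other. Where tiles were grouped by their D0 level, the class was taken from 1 replicate and the values from the other, so that the selection did not shape the values.

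The test was tried on simulated data before use. In 20000 tiles simulated as iPSC against D0, edgeR recovered 4.5% of changes of 15 points, 55.2% of changes of 25 points and 100% of changes of 40 points, and called 2 unchanged tiles. The quasi-binomial logistic model used as an alternative (limma 3.58.1 for the moderated overdispersion) recovered 28.4%, 83.6% and 100% of the same changes and called 26 unchanged tiles. Only 67, 67 and 66 of the tiles were changed, by 15, 25 and 40 points, and the overdispersion was set by choice and not fitted to the data. The shares recovered and the false calls hold for that setting and do not carry over to contrasts in which far more tiles were called. Alternatives were a site coverage minimum of 20 reads, strands merged, the quasi-binomial model, a replicate block, a fit of the compared groups alone, a minimum difference of 25 points, sites common to the compared groups only, a read-weighted global mean and leaving out each library in turn. Tiles of 500 bp and the removal of the sites of highest coverage were added after seeing the data. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.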

Results

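Reprogramming of fibroblasts to pluripotent cells with small molecules was followed by RRBS of genomic DNA. The starting cells (D0) were mouse embryonic fibroblasts (MEFs) from embryos of a cross with OG2 mice, a strain that carries a fluorescent reporter of the pluripotency factor Oct4. The cells were placed in reprogramming medium and collected every 2 days up to day 12, and induced pluripotent stem cells (iPSCs) were sequenced along with them. The labels do not say from which culture or day the iPSCs came. The iPSCs were kept on feeder cells, in medium with LIF, the GSK3 inhibitor CHIR99021 and the MEK inhibitor PD0325901. Whether feeder cells were removed before DNA extraction is not given in the sources used here. Each of the 8 groups had 2 libraries. The sum of coverage over the listed CpG sites ranged from 39011213 reads in D6 replicate 1 to 107834007 reads in D0 replicate 1, and the comparisons below rest on the 873038 sites with at least 10 reads in each library.

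The first question was how the methylation level of the common sites moved over the time course. Mean methylation was 51.2% ± 0.094 (SD, n = 2) in MEFs, 48.6% ± 0.017 at D2 and 50.4% ± 0.0072 at D4. It was 43.1% ± 0.41 at D6, 32.9% ± 0.76 at D8, 25.0% ± 0.28 at D10 and 17.8% ± 0.061 at D12. Over the common sites the D12 mean was thus 34.9% of the MEF mean. In iPSCs the mean was 47.9% ± 0.089, which was 93.6% of the MEF mean. Over all sites that each library listed, the level was 55.1% and 54.1% in the D0 libraries and 28.4% and 28.8% at D10. It was 27.8% and 26.5% at D12 and 50.4% and 50.1% in iPSCs. The listed sites differ between libraries, and the size of the fall depended on the sites counted. The share of highly methylated sites moved in the same direction. Sites at 80% methylation or more made up 38.7% ± 0.035 of the common sites at D0, 20.0% ± 0.35 at D6, 5.17% ± 0.52 at D8 and 0.322% ± 0.010 at D12, and 33.4% ± 0.064 in iPSCs. Sites between 20% and 80% went from 25.0% ± 0.35 at D0 to 55.0% ± 0.53 at D8 and stood at 36.3% ± 0.12 at D12, while sites under 20% went from 36.4% ± 0.39 at D0 to 63.3% ± 0.13 at D12.

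**Figure D1:**
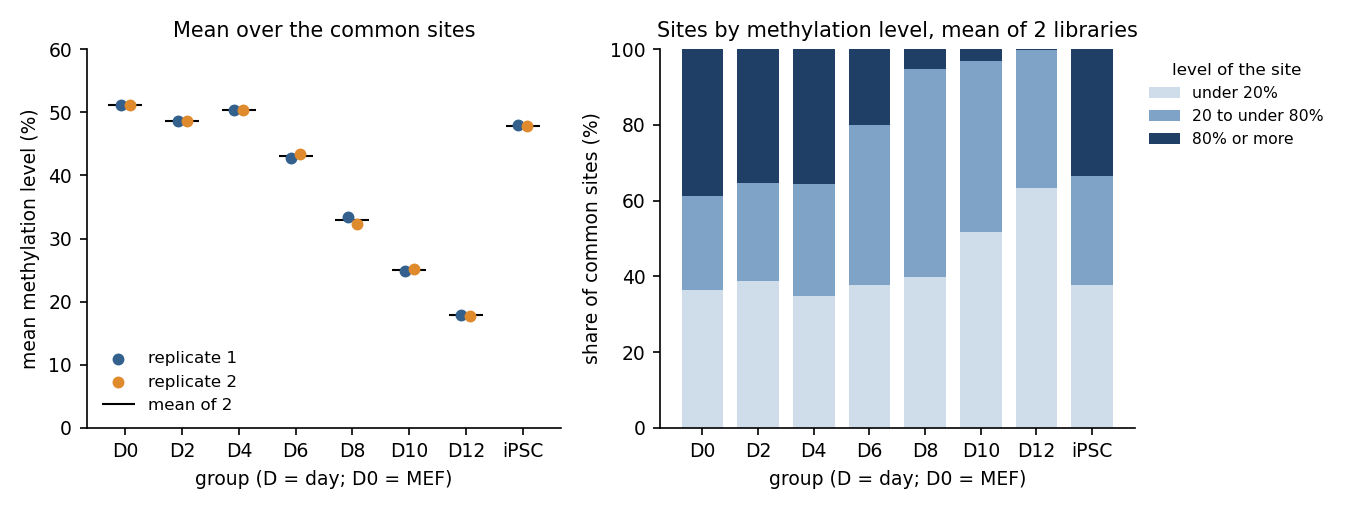
Mean methylation level over the common sites in each library (left, y axis in percent, points for replicates, bars for the mean of 2) and the share of common sites in 3 ranges of methylation (right, y axis in percent of sites, mean of 2 libraries), by group. The level lies at 51.2% in D0 and 17.8% in D12, and sites at 80% or more make up 0.322% of the sites in D12 and 33.4% in iPSCs.

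Over the 14 libraries from D0 to D12 the global level fell with day, with Pearson r = -0.953 and Spearman rho = -0.957 (permutation p = 1e-05 for both, adjusted 1e-05 over the 2 coefficients, the smallest value these permutations give). The permutations treat the 2 libraries of a day as independent, although they lay close to each other, so these p-values overstate the evidence. No test over the day means was made. Without the D0 libraries r was -0.970, and without the D12 libraries it was -0.926. The D12 mean differed from the D0 mean by -33.3 points ± 0.079 (SE) and the iPSC mean by -3.29 points ± 0.092, while iPSCs lay 30.1 points ± 0.076 above D12. In all 3 comparisons the libraries of the groups did not overlap, and the exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 allow.

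The time at which individual regions changed was read from the 1-kb tiles. Few tiles passed the thresholds at D2 or D4. At D2, 46 of 94337 tiles were called, each of them lower, and the median difference of all tiles was -2.20 points. The background, the mean level of 4542 tiles under 15% in all libraries, was also lower at D2, at 3.34% ± 0.030 against 4.59% ± 0.013 at D0. At D4, 76 tiles were called, of which 72 were lower. At D6, 20063 tiles (21.3%) had fallen and 98 had risen. At D8 the counts were 68204 lower and 513 higher, and at D10 they were 77013 lower and 190 higher. A joint test of D0 to D12 called 79340 tiles, or 84.1%. These calls come from edgeR with Benjamini-Hochberg adjustment.

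The early counts were the least stable. In the simulation 4.72% of unchanged tiles reached an unadjusted p under 0.05 in edgeR, so counts at that p do not by themselves show change. That share covers both directions and has no minimum difference, so it is not a direct reference for the D2 counts that follow, which are split by direction. The excess of lower over higher tiles at D2 was not tested. At D2, 6494 tiles lay at least 10 points below D0 and 644 at least 10 points above, and 2601 of the lower ones had an unadjusted p under 0.05 in edgeR. In the comparison of D2 with D0, no tile was called higher, although 119 tiles reached an unadjusted p under 0.05 in edgeR with a difference of 10 points, and the quasi-binomial model also called 0 higher and 353 lower. Leaving out any library of D0, D2 or D4, or fitting the compared groups alone, left 0 calls at D2 and D4, with between 2058 and 5844 tiles at an unadjusted p under 0.05. The D6 count was 5526 and 7509 without D6 replicate 1 and 2, and 2420 and 2286 without D0 replicate 1 and 2. It was 31853 under the quasi-binomial model and 3559 with a minimum of 25 points, and the quasi-binomial model called 771 tiles at D4.

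Loss of methylation between MEFs and D12 reached most of the measured genome. Of the tiles, 77995 (82.7%) were lower at D12 and 612 (0.649%) were higher, and 38634 tiles had fallen by 50 points or more. The higher count was 1181 under the quasi-binomial model and also 1181 with sites common to D0 and D12 only, 197 with at least 20 reads per site and 73 with a minimum of 25 points. The tiles called lower had a mean level of 67.5% ± 0.12 (SD, n = 2) in MEFs, 55.6% ± 0.36 at D6 and 18.9% ± 0.079 at D12, and the same tiles stood at 63.8% ± 0.16 in iPSCs. The loss was spread over the chromosomes. Tiles retained between 29.4% (chromosome 9) and 31.8% (chromosome 13) of their MEF level on the 19 autosomes, 32.0% on X and 33.5% on Y. Tiles on Y had a mean level of 73.4% ± 0.49 at D0, 24.6% ± 0.81 at D12 and 73.3% ± 1.1 in iPSCs.

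By tile, the largest decreases at D12 went from nearly full to nearly no methylation. A tile on chromosome 2 (165134001 to 165135000) was at 94.0% ± 1.7 in MEFs and 0% ± 0 at D12 (adjusted p = 1.35e-05, edgeR), over 3 sites with 53 to 120 reads per library. It was at 98.1% ± 2.7 in iPSCs. A tile on chromosome 5 (112534001 to 112535000) was at 95.1% ± 0.29 in MEFs and 2.67% ± 1.6 at D12 (adjusted p = 6.54e-08), over 5 sites with 85 to 371 reads. The other named decreases lay on chromosome 3 (97140001 to 97141000), chromosome 4 (148764001 to 148765000) and chromosome 1 (150768001 to 150769000), with differences of -93.3, -92.6 and -92.3 points. The longest runs of adjacent tiles called lower at D12 held 6 tiles, on chromosome 4 (146416001 to 146422000), chromosome 18 (37885001 to 37891000) and chromosome 19 (47496001 to 47502000). On chromosome 19 the mean level of the run was 75.1% in MEFs, 18.2% at D12 and 64.7% in iPSCs.

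Tiles that were higher at D12 were few and started low. The 612 tiles had a mean level of 5.98% ± 0.19 in MEFs, 14.2% ± 0.26 at D4, 11.2% ± 0.012 at D10, 23.5% ± 0.070 at D12 and 9.34% ± 0.22 in iPSCs. These means come from the libraries that selected the tiles, which widens the difference. When tiles at least 10 points higher at D12 were chosen in 1 replicate and measured in the other, the level went from 10.96% at D0 to 16.1% at D12 (2274 tiles, measured in replicate 2) and from 10.4% to 15.6% (2339 tiles, measured in replicate 1). The 612 tiles were CpG-rich, with a median of 22 CpGs listed, against 6 in all tiles. CpG-rich tiles started lower in general, with a mean of 25.7% at D0 for 20 or more CpGs and 60.7% for 1 to 4. The CpG number of the 612 tiles was not compared with that of other tiles of low MEF level, so it may reflect their low start. The largest increase, on chromosome 17 (5045001 to 5046000), went from 0% ± 0 in MEFs to 59.5% ± 23 at D12, so that the D12 replicates lay far apart (edgeR adjusted p = 0.0193). The next ones lay on chromosome 5 (142891001 to 142892000, +44.7 points), chromosome 17 (46795001 to 46796000, +42.1 points), chromosome 19 (5618001 to 5619000, +41.1 points) and chromosome 10 (44144001 to 44145000, +40.5 points). All of these except the tile at 46795001 lost their call when the strands were merged (differences of 18.6 to 27.0 points, adjusted p = 0.0778 to 0.363) and with sites common to D0 and D12 only (18.6 to 24.3 points, adjusted p = 0.0783 to 0.406). The tiles at 5045001 and 5618001 also lost it without D12 replicate 2 or without D0 replicate 1, and the tile at 5618001 without D0 replicate 2 (adjusted p = 0.0513 to 0.154). Without D12 replicate 2 the differences were 43.0 points at 5045001 and 23.4 points at 5618001. Without D0 replicate 1 they were 59.5 and 43.3 points, and without D0 replicate 2 the difference at 5618001 was 39.0 points, so without a D0 library the differences stayed about as large and it was the adjusted p that rose above 0.05. Methylation of tiles that were low in all libraries, the background of the assay, was 4.59% ± 0.013 at D0, 5.06% ± 0.017 at D4, 3.74% ± 0.14 at D10, 4.99% ± 0.012 at D12 and 4.02% ± 0.057 in iPSCs.

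**Figure D2:**
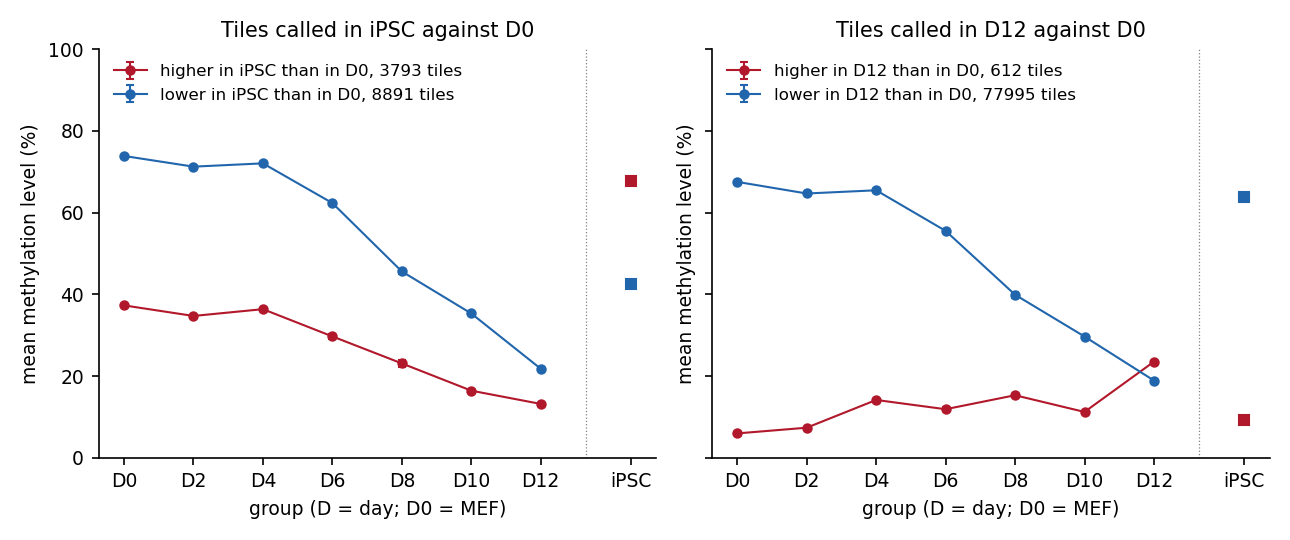
Mean methylation level (y axis, percent) by group of the tiles called higher (red) and lower (blue) in iPSCs than in D0 (left) and in D12 than in D0 (right). Points are means of 2 libraries with SD bars, mostly smaller than the points; the 3793 tiles called higher in iPSCs stood at 13.2% at D12 and at 67.8% in iPSCs.

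Whether iPSCs carried another methylation pattern than the MEFs was asked next. The median difference between iPSCs and MEFs was -1.76 points over all tiles, and 12684 tiles (13.4%) were called. Of the 94337 tiles, 8891 (9.42%) were lower in iPSCs than in MEFs and 3793 (4.02%) were higher, and 1082 and 306 of these differed by 50 points or more. The tiles called lower had mean levels of 73.9% ± 0.16 in MEFs, 21.8% ± 0.071 at D12 and 42.5% ± 0.012 in iPSCs. The tiles called higher had mean levels of 37.3% ± 0.017 in MEFs, 13.2% ± 0.22 at D12 and 67.8% ± 0.19 in iPSCs.

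Losses in iPSCs were most frequent in tiles with many CpGs. Lower calls made up 4.46% of tiles with 1 to 4 CpGs, 10.1% with 5 to 9, 15.1% with 10 to 19 and 12.2% with 20 or more. Higher calls made up 3.63%, 5.17%, 3.97% and 1.30% of the same classes. On X, 200 tiles were lower and 16 higher of 1830, that is 10.9% and 0.874%, against 9.40% and 4.09% on autosomes. The difference between X and autosomes was not tested.

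Among the named tiles, the largest gain in iPSCs lay on chromosome 8 (103280001 to 103281000). It rose from 5.97% ± 0.28 in MEFs to 89.5% ± 1.5 in iPSCs (edgeR adjusted p = 0.000191), over 3 sites with 78 to 146 reads per library, and was at 12.7% at D12. The others were on chromosome 3 (79649001 to 79650000), chromosome 1 (192480001 to 192481000), chromosome 10 (120553001 to 120554000) and chromosome 14 (24901001 to 24902000), with gains of 75.6 to 81.8 points. The tile on chromosome 10 was no longer called without iPSC replicate 2 (+73.5 points, adjusted p = 0.0561) or without D0 replicate 1 (+75.01 points, adjusted p = 0.0554), although the difference stayed near the +76.2 points of the main fit. The largest loss lay on chromosome 12 (91440001 to 91441000), which went from 97.1% ± 4.2 to 2.38% ± 3.4 over 3 sites with 34 to 42 reads (adjusted p = 8.94e-05) and was at 33.3% at D12. A tile on chromosome 4 (126127001 to 126128000) fell from 92.4% ± 0.22 to 0% ± 0 (adjusted p = 0.00108) and was at 7.62% at D12. The remaining losses, on chromosome 8 (58548001 to 58549000), chromosome 6 (93354001 to 93355000) and chromosome 10 (104590001 to 104591000), were of -88.9, -87.4 and -86.8 points.

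Adjacent tiles were called in the same direction in places. The longest run of tiles lower in iPSCs held 5 tiles on chromosome 17 (35817001 to 35822000), at 67.7% in MEFs, 45.0% at D12 and 36.1% in iPSCs. The longest run of tiles higher in iPSCs held 4 tiles on chromosome 4 (154555001 to 154559000), at 40.7% in MEFs, 10.9% at D12 and 72.1% in iPSCs. Runs of at least 3 tiles numbered 56 among the losses and 5 among the gains. How many runs would arise if calls fell at random was not computed.

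The number of iPSC calls moved with the number of libraries and the settings. The higher count was 5978 under the quasi-binomial model, the counts were 2326 higher and 5347 lower with a minimum of 25 points, and 2431 and 5523 with at least 20 reads per site, where 47199 tiles remained. Leaving out 1 library of D0 or iPSC gave 1784 to 1915 tiles higher and 5559 to 6061 lower, so the higher count fell by more than 1.5 times without any of the 4 libraries, and the lower count did so without either D0 library (5570 without D0 replicate 1 and 5559 without D0 replicate 2).

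The iPSCs were then compared with the D12 cells. Methylation was higher in iPSCs than at D12 in 75261 tiles (79.8%) and lower in 1397 (1.48%). The lower count was 222 with a minimum of 25 points and 493 with at least 20 reads per site. The tiles called higher were at 18.5% ± 0.083 at D12, 65.7% ± 0.18 in iPSCs and 66.8% ± 0.12 in MEFs. The tile on chromosome 2 (165134001 to 165135000) also led this comparison, with a difference of +98.1 points (edgeR adjusted p = 1.5e-05). The other named tiles, with differences of 90.1 to 91.2 points, lay on chromosome 17 (30163001 to 30164000), chromosome 1 (150768001 to 150769000) and chromosome 13 (68855001 to 68856000 and 56924001 to 56925000).

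Some tiles were lower in iPSCs than at D12. The tiles called lower in iPSCs than at D12 were at 27.2% ± 0.17 in MEFs, 30.1% ± 0.028 at D4, 21.6% ± 0.11 at D10, 26.4% ± 0.11 at D12 and 8.10% ± 0.29 in iPSCs. The D12 and iPSC means come from the libraries that selected the tiles, which widens the difference. Similar means in MEFs and at D12 do not show that each tile kept its level. These calls made up 7.23% of tiles with 20 or more CpGs and 0.135% of those with 1 to 4. Whether incomplete conversion contributes was not tested for them. A tile on chromosome 8 (58548001 to 58549000) was at 98.3% in MEFs, 80.1% ± 1.5 at D12 and 9.33% ± 13 in iPSCs (edgeR adjusted p = 0.00089), over 3 sites with 39 to 105 reads. A tile on chromosome 5 (93090001 to 93091000) was at 93.0% in MEFs, 86.7% ± 19 at D12 and 27.8% ± 5.0 in iPSCs (adjusted p = 0.00629). It missed the threshold when D12 and iPSC were fitted alone (adjusted p = 0.0526), with the same difference of -58.9 points. The others were on chromosome 10 (104590001 to 104591000 and 86070001 to 86071000) and X (20628001 to 20629000), with differences of -59.3, -49.4 and -53.2 points. With the strands merged or with sites common to D12 and iPSC only, the difference on chromosome 8 was -37.9 or -42.4 points and that at 104590001 was -38.2 or -25.1 points, and both tiles were still called.

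The changes at D12 and in iPSCs, both against MEFs, were set side by side on tiles chosen in replicate 1 and read in replicate 2. In 8461 tiles that were at least 20 points lower in iPSCs, the median of the D12 change over the iPSC change was 1.56, because the D12 level was 51.9 points below MEFs in the median and the iPSC level 29.7. Over all tiles the median D12 change was already -45.9 points, so a value above 1 can arise from the general loss alone and does not show a move towards the iPSC pattern. In 4783 tiles that were at least 20 points higher in iPSCs, the median was -0.792, since the D12 level was 23.3 points below MEFs where the iPSC level was 26.0 points above. With selection at 40 points the median for gains was -0.290 over 964 tiles. Over both kinds of tiles together the median was 1.05. No test was made of these medians.

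The D12 level as a percent of the MEF level, called retention here, varied with starting level and with CpG number. Tiles at 10% to 20% in MEFs stood at 93.0% of their MEF level at D12, tiles at 20% to 40% at 40.5% and tiles at 40% to 60% at 27.1%. Retention was lowest, at 26.2%, in tiles at 60% to 80%, and was 30.8% at 80% to 90% and 36.2% at 90% to 100%. Tiles under 10% in MEFs had 6.39% at D0 and 8.54% at D12, which is above the MEF level. Tiles at 10% to 20% had 13.1% at D0, 9.43% at D10 and 12.2% at D12, measured in replicate 2, near the level of the tiles under 10%. Their 93.0% can therefore include background signal and is not a measure of retained methylation alone. The same holds for tiles at 20% to 40% and 40% to 60%, which stood at 12.5% and 14.1% at D12 in replicate 2. Across these classes the D12 level moved little while the D0 level rose, so the falling percent mainly follows the D0 level. Within the class of 80% to 90%, tiles with 1 to 4 CpGs kept 25.5%, those with 5 to 9 CpGs 29.7%, those with 10 to 19 CpGs 34.0% and those with 20 or more CpGs 37.9%. With the replicates exchanged these were 25.9%, 29.7%, 33.7% and 37.3%. On 19 of 19 autosomes the tiles with 20 or more CpGs kept more than those with 1 to 4. The order was the opposite in iPSCs, where the same 4 classes stood at 93.4%, 90.3%, 86.1% and 78.7% of their MEF level.

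**Figure D3:**
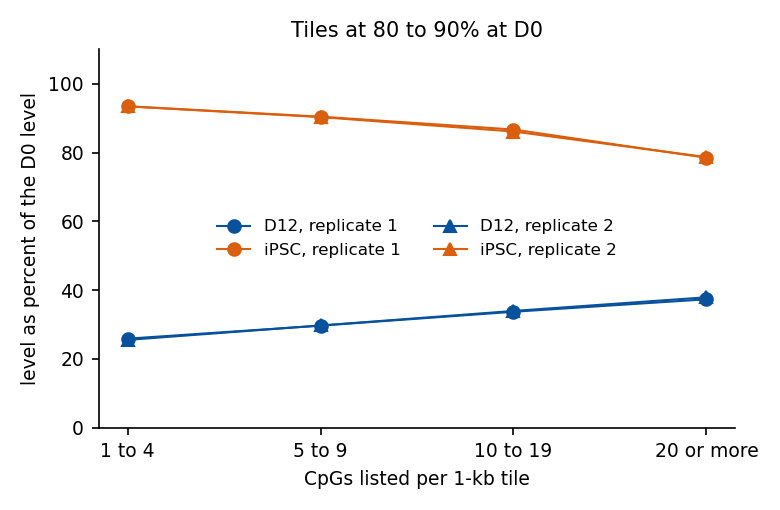
Methylation level at D12 (blue) and in iPSCs (orange) as a percent of the D0 level (y axis) in tiles at 80% to 90% at D0, by the number of CpGs listed per tile (x axis). Each point is 1 replicate, with tiles chosen in the other; D12 goes up from 25.5% to 37.9% and iPSC goes down from 93.4% to 78.7% in replicate 2.

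A small set of tiles stood above 50% in both D12 libraries. These were 571 tiles (0.605%), with means of 89.0% ± 0.13 in MEFs, 60.1% ± 0.27 at D12 and 77.3% ± 0.082 in iPSCs. The D12 mean was read from the libraries that selected the tiles, which raises it. Tiles above 50% in D12 replicate 1 (1669 tiles) had 82.6% at D0 and 43.5% at D12 in replicate 2, and those above 50% in D12 replicate 2 (1638 tiles) had 82.7% and 44.5% in replicate 1. Of the 571 tiles, 478 were above 50% in both iPSC libraries and 58 were below 50% in both. X held 44 of them, or 2.40% of its tiles, against 0.567% on autosomes. Among tiles at 80% or more in MEFs the shares were 7.82% on X and 2.57% on autosomes. Of the tiles above 50% in 1 D12 library, 74 of 1669 (replicate 1) and 85 of 1638 (replicate 2) lay on X, a smaller part than 44 of 571. No test of X against autosomes was made. The highest level at D12 was 92.3%, on chromosome 11 (19970001 to 19971000), which was at 97.7% in MEFs and 81.5% in iPSCs, over 10 sites with 120 to 1043 reads per library. On X, a tile with 30 sites (169084001 to 169085000) was at 97.2% in MEFs, 82.2% at D12 and 94.4% in iPSCs. These 2 tiles were picked after their values were seen.

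CpG-rich tiles of X were more methylated than those of the autosomes in MEFs. With 20 or more CpGs, 154 tiles of X had a mean level of 42.4% ± 0.018 in MEFs, 21.7% ± 0.25 at D12 and 32.4% ± 0.52 in iPSCs. The 9254 autosomal tiles of that class had 25.4% ± 0.11, 15.2% ± 0.0094 and 20.4% ± 0.20. In tiles with 1 to 4 CpGs, X and autosomes were at 61.0% ± 0.13 and 60.7% ± 0.19 in MEFs and at 60.15% ± 0.56 and 60.01% ± 0.22 in iPSCs. Reads on X, as a percent of autosomal reads, were 1.81 ± 0.020 in MEFs and 1.62 ± 0.00037 in iPSCs, and reads on Y per 1000 autosomal reads were 1.16 ± 0.040 and 1.20 ± 0.0044. Reads on Y were present in each library, and the sex of the embryos is not given in the labels.

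**Figure D4:**
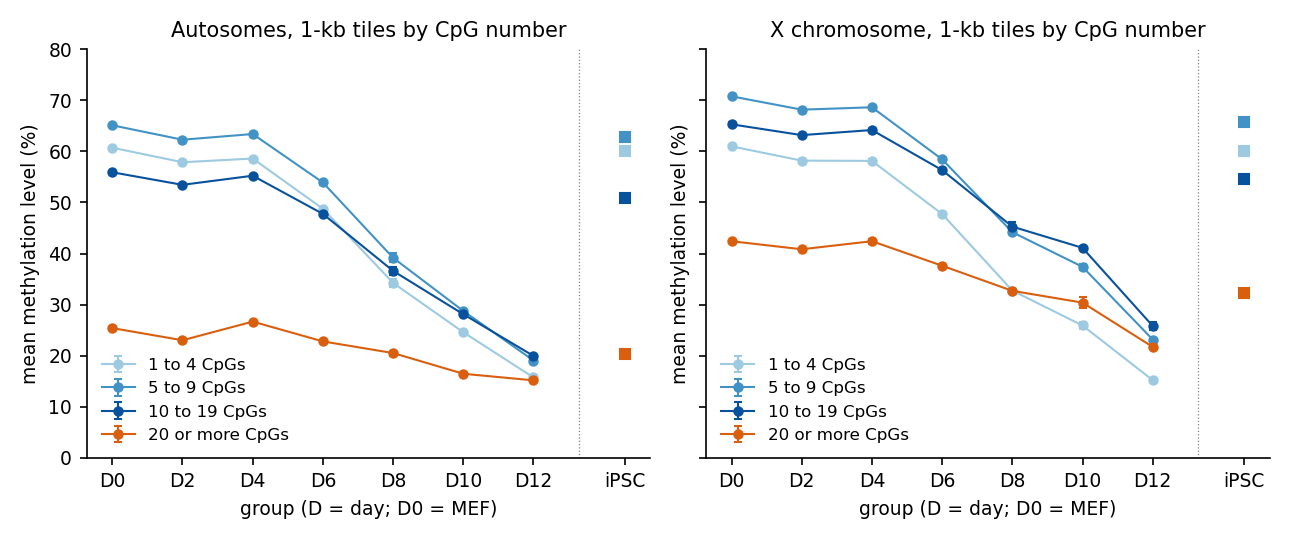
Mean methylation level (y axis, percent) by group of 1-kb tiles in 4 classes of CpG number, on autosomes (left) and X (right). Points are means of 2 libraries with SD bars; tiles with 20 or more CpGs lie at 42.4% on X and 25.4% on autosomes in D0, and at 21.7% and 15.2% in D12.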

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

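Of the tests in this part, the comparison of the tiles higher at D12 with each library's background, the comparison with D4 and D8 in split replicates, and the match on read depth were set before their results were seen. The others were chosen only after the pattern was seen.

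Signals on chromosome M, outside the nuclear sites, stood above the MEF level in some groups and below it in others, judged by libraries that did not overlap with those of D0. At the 15 sites of chromosome M covered in all libraries the level was 5.81% ± 0.027 (SD, n = 2) in D0, 8.01% ± 1.8 in D4, 7.03% ± 1.5 in D6, 9.17% ± 1.8 in D8 and 7.88% ± 0.14 in D12. It was lower than in D0 in D2 (4.49% ± 0.20), D10 (5.25% ± 0.018) and iPSCs (4.56% ± 0.51). Over the 8 group means it followed the level of the low nuclear tiles, with r = 0.856 and rho = 0.881 (exact permutation p = 0.0117 and 0.00724, adjusted 0.0175 and 0.0145 over 6 coefficients). Without the 2 groups farthest from the median r was 0.800 over 6 group means (exact permutation p = 0.0681). The larger p can come from the smaller number of means, so it does not show whether the relation rests on those groups. Reads on these sites per 1000000 reads on the common nuclear sites were 614 ± 21 in D0, 388 ± 3.5 in D2, 998 ± 70 in D4, 2121 ± 308 in D6, 1526 ± 302 in D8, 3544 ± 45 in D10, 2231 ± 90 in D12 and 1034 ± 59 in iPSCs. With 2 libraries per group no group was large enough for a search for single outlying libraries.

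The fall of methylation from D0 to D12 was the largest pattern. More complete bisulfite conversion at D12 would lower the level of chromosome M, whose sites were not chosen by level, but it was 2.07 points ± 0.15 higher at D12 than in MEFs. The percent retained differed by 11.9 points between CpG-rich and CpG-poor tiles that started at 80% to 90%. This argues against a loss of the same proportion of calls at each site. It does not exclude such a loss together with a background signal that is larger in CpG-rich tiles, which was not tested. A growing share of cells like the iPSCs would put D12 between D0 and iPSC, where its mean did not lie, and would lower the tiles that iPSCs lost. Matched on MEF level and CpG number, tiles at least 40 points lower in iPSCs differed at D12 by -1.03 points ± 0.096 from tiles within 10 points. These values argue against such cells as the main source of the fall. The difference exceeded its spread in the direction such cells would give, so a small share of them is not excluded. A biological loss of methylation in the reprogramming cells, the difference the design names, remains as a hypothesis, with no test of how the cells would lose it.

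The tiles higher at D12 than in MEFs were less secure. Tiles at least 10 points higher at D12 in 1 replicate rose by 5.17 points in the other. This was 3.00 points ± 0.020 more than the 2.18 points of tiles chosen only for a level under 10% in 1 MEF library. The values argue against a library-wide shift of background by the same number of points in each tile. The 2 sets were not matched on MEF level (10.96% and 6.39% at D0, measured in replicate 2) or on CpG number. A shift that grows with either of these was therefore not excluded. Local incomplete conversion may contribute: over the 12 libraries of the other 6 groups the mean level of these tiles followed the background with r = 0.916 (rho = 0.860, permutation p = 0.00016 and 0.00077, adjusted 0.00096 and 0.0023 over 6 coefficients), and r was 0.880 without the 2 libraries farthest from the median. Replicates of a group are close to each other, and over the 6 group means r was 0.920 (exact permutation p = 0.0167). Without the 2 groups farthest from the median it was 0.753 (4 means, exact permutation p = 0.25). With only 4 means this does not show how far the relation rests on those groups. When tiles were chosen in 1 replicate and measured in the other, D12 exceeded the higher of D4 and D8 by 0.938 points ± 0.68, and these values do not decide whether incomplete conversion alone gives the increase.

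The higher retention of CpG-rich tiles at D12 was tested against 2 technical explanations. A higher starting level was excluded, since tiles with 20 or more CpGs lay 9.53 points above tiles with 1 to 4 CpGs within 2-point classes of the MEF level. A difference in read depth was excluded too, since the difference was 9.55 points within classes of both MEF level and reads per site. Filled-in cytosines at MspI ends were not tested, because the sites were not placed on the genome sequence. Local incomplete conversion, left open above for the tiles higher at D12, which were CpG-rich, was not tested for this pattern either. That CpG-rich regions lose methylation more slowly in these cells is a hypothesis, and iPSCs, in which CpG-rich tiles stood lower, do not show the same order.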

How the results depend on the processing

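Tiles of 500 bp and the removal of the sites of highest coverage were chosen after seeing the data. Minimum coverage below 10 reads, the omission of MspI sites, another promoter window, and all alternatives for promoters, CpG islands, gene lists, imprinting windows and named genes were not run. The global differences and the correlation with day kept their sign under all alternatives (D12 minus D0 -39.0 to -31.9 points, iPSC minus D0 -3.56 to -2.90). Depth limited which sites were compared, 27.5% of those listed, and no simulation varied it.

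With 20 reads per site 47199 tiles remained, and the counts were 2431 higher and 5523 lower in iPSC against D0, 197 and 38641 in D12 against D0, 37268 and 493 in iPSC against D12, 22 called at D2, 86 at D4, 14845 at D6 (31.5% of these tiles against 21.4%), 35892 at D8, 38304 at D10 and 39166 in the joint test. The quasi-binomial model called 5978 higher in iPSC against D0, 1181 higher in D12 against D0, and 353, 771 and 31853 at D2, D4 and D6. A minimum of 25 points gave, by construction, 2326 higher and 5347 lower in iPSC against D0, 73 higher in D12, 222 lower in iPSC than in D12 and 3559 at D6. Sites common to the compared groups gave 1181 higher at D12, 27 at D2 and 44 at D4. Fitting 2 groups alone called 0 at D2 and 0 at D4 (edgeR, with 4522 and 5844 tiles at an unadjusted p under 0.05). At 20 reads the D12 higher calls were 0.417% of tiles against 0.649%, and the D4 count rose, so fewer tiles do not explain all moves. Beyond the number of tiles, libraries or points set by an alternative, the cause was not tested.

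The replicate numbers do not pair the libraries: 28 correlations of deviations between same-numbered libraries lay between -0.0144 and 0.00778. With a replicate block the D2 and D4 counts were 25 and 48, and the other counts stayed within 1.5 times (3588 higher and 8619 lower in iPSC against D0).

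Without 1 library, assuming that the lone sample varies like the other groups, the counts were 1784 to 1915 (higher) and 5559 to 6061 (lower) in iPSC against D0, 522 to 627 and 76361 to 76986 in D12 against D0, 73490 to 74080 and 1190 to 1341 in iPSC against D12, 0 to 0 at D2 and at D4 (edgeR; 2058 to 3633 at an unadjusted p under 0.05; quasi-binomial model with all libraries, 353 and 771), 2286 to 7509 at D6, 59942 to 63821 at D8, 73696 to 74589 at D10 and 78168 to 79487 in the joint test. The share of the iPSC change reached at D12 was 1.0522 for all tiles, 1.5606 for losses and -0.7757 for gains when selected in replicate 2, and 0.9377, 1.1231 and -0.2896 with selection at 40 points. Of 331 values of the 30 named tiles under alternatives, 315 kept direction and call, 16 kept the direction without the call and 0 reversed.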

Other observations

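Coverage of the sex chromosomes differed between groups. Reads on the common sites of X, as a percent of reads on autosomal sites, were 1.81 ± 0.020 (SD, n = 2) in D0, 2.12 ± 0.057 in D4, 1.78 ± 0.019 in D12 and 1.62 ± 0.00037 in iPSCs. Reads on Y per 1000 autosomal reads were 1.16 ± 0.040 in D0, 1.12 ± 0.058 in D4, 1.04 ± 0.023 in D12 and 1.20 ± 0.0044 in iPSCs. The iPSC libraries thus had the lowest coverage of X and the highest of Y among the 8 groups, and no test of the difference was made.

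Tiles of intermediate methylation in both MEFs and iPSCs were followed through D12, since parental imprints give such levels. Between 35% and 65% in all D0 and iPSC libraries lay 1279 tiles with 10 or more CpGs. Their mean was 53.1% in D0, 17.1% in D12 and 52.0% in iPSCs. Of these, 26 (2.03%) were also between 35% and 65% in both D12 libraries, for example a tile on chromosome 2 (120109001 to 120110000) at 63.6% in D0, 45.9% in D12 and 56.9% in iPSCs. Whether any of them lies at an imprinted gene was not looked up, and the example was picked after its values were seen.

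D4 replicate 1 listed 430 sites on chromosome M, with a level of 30.5%, where the other libraries listed 18 to 175 sites, with levels of 4.35% to 11.4%. At the chromosome M sites covered in all libraries D4 replicate 1 was at 9.31%, D4 replicate 2 at 6.71% and D8 replicate 1 at 10.5%.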
